A study of Mus musculus with 16 samples.

How the data were processed

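RNA was sequenced from adoptively transferred mouse CD8 T cells recovered from tumours by sorting. The cells were OT1 cells, which carry a transgenic receptor for an ovalbumin peptide, on the C57BL/6 background. The labels define 4 groups of 4 libraries each: Foxp3UP and its control MockUP, and Foxp3DN and its control MockDN. The labels do not say what UP and DN stand for, nor how Foxp3 expression was imposed, so both are used here as names only. Per the labels' protocols, RNA was isolated with a Maxwell tissue kit and libraries followed standard Illumina protocols.

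The authors deposited raw read counts per gene in 1 table with 1 column per library. The submitters' processing notes name STAR 2.6.1, Subread 1.6.3 and the mouse genome build mm10, and per the file headers the table also holds each gene's coordinates and exonic length. The counting options, the use of strand and the annotation release are not given in the sources used here. Reads of overlapping or antisense genes may therefore be shared. Members of near-identical families (such as the Oas, Ifi27, Gapdh, granzyme and Ly6 genes) are uncertain for the same reason. Of the 55573 gene identifiers, 55480 were found in GENCODE release M21, and 55304 had the same start and end there. Gene symbols came from that release, and coordinates are those of the deposited table on mm10, counted from 1. Each column was matched to a sample by the sample number in the sample's title. No column held another sample, and no library repeated another.

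Library totals ran from 9389477 to 13226590 counts. Genes were kept with the filterByExpr function of edgeR at its minimum count of 10, which left 13711 genes. Counts were scaled by TMM and tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood F test with robust dispersion over all 16 libraries and a term per group. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of F, and its median over all genes was 0.18 in Foxp3UP against MockUP. Levels are given as TMM-scaled CPM, as mean ± SD with n = 4. The comparisons made were Foxp3UP against MockUP, Foxp3DN against MockDN, the difference between those effects, and MockUP against MockDN. Foxp3 alone was also tested on log2(CPM + 0.5) with a two-sided exact permutation test.

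Gene lists, 22 of T cell functions and metabolism and 9 of markers of other cells, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with the correlation between genes preset at 0.01. Camera with an estimated correlation and fry were alternatives. Lists with fewer than 3 measured genes were not tested as sets, which left 29. The groups, the tests, the lists, the rule for named genes and most of the alternative settings were fixed before the data were examined. The rule named 16 fixed genes whatever their result. It then took the 8 higher and 8 lower called genes with the largest fold change, an average log2 CPM of at least 1 and no overlap between the groups' libraries, leaving out predicted or unnamed genes. Last, it took up to 4 called members of each list with the smallest adjusted p. The overlap condition was not used for the difference of effects, and 4 genes per direction were taken for MockUP against MockDN. Other genes are named in places and were then chosen after their values were seen. The results of some single genes are not reported here.

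The replicate numbers in the titles were checked as pairs. Deviations from the group means correlated between same-numbered libraries at 0.630, 0.213, 0.297 and 0.398 in the UP arm and 0.364, 0.582, 0.545 and 0.298 in the DN arm. Among the Mock libraries of its arm, each Foxp3 library correlated best with the one of its own number. The margin was small for Foxp3UP 2, 3 and 4, where the highest other correlations were 0.173, 0.220 and 0.364. A fit with the replicate number as a block was therefore set beside results that it changes. Sample numbers in the titles also place replicates 1 and 2 of all groups before replicates 3 and 4, and values within these sets are given too.

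The steps were tested on simulated counts drawn from the real means and library sizes. Each library was drawn independently, without the pairs and sets of replicates seen in the real libraries, so real recovery may differ. For Foxp3UP against MockUP, with 13527 genes, edgeR recovered 20.9% of 1.5-fold, 79.1% of 2-fold and 90.9% of 4-fold changes, and 7 of 134 calls were false. For Foxp3DN against MockDN, with 13521 genes, it recovered 20.9%, 70.1% and 89.4%, and 5 of 125 calls were false. For the difference of effects, with 13532 genes, it recovered 8.96%, 44.8% and 81.8%, and 3 of 93 calls were false. For MockUP against MockDN, with 13539 genes, it recovered 19.4%, 62.7% and 89.4%, and 10 of 124 calls were false. The alternative settings fixed then were RLE size factors, library totals, no filter and a stricter filter (at least 1 CPM in 4 libraries), DESeq2 1.42.0, limma-voom and non-robust dispersion. They also included only the libraries compared, the replicate block, a term for replicates 1 and 2 against 3 and 4, each library left out in turn, mitochondrial genes left out, and a 2-fold threshold. Removal of a gene length trend, fits to each set of replicates alone and the block without MockUP 2 were chosen after seeing the data. Nothing in the labels says that the replicates of a group are separate animals, so p-values measure only the spread between these samples, which may be technical.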

Results

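Tumour-bearing mice had received a mixture of Foxp3UP and Mock CD8 T cells, and the transferred cells were sorted from the tumours 5 days later by viability, CD8, CD45.1 and/or CD90.1. The series asks which changes, including metabolic ones, accompany expression of Foxp3, the lineage transcription factor of regulatory T cells, in CD8 T cells used for therapy. The 16 libraries comprised 4 in each of the groups Foxp3UP, MockUP, Foxp3DN and MockDN. Mean totals were 10853771 ± 1143500 counts in Foxp3UP, 10001000 ± 471869 in MockUP, 11677670 ± 1305820 in Foxp3DN and 11782800 ± 931741 in MockDN (SD, n = 4 each). Between 19847 and 20763 genes had at least 1 count in a library.

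The first principal component of log2 CPM held 34.3% of the variance and the second 18.7%. The first set replicates 1 and 2 of each group below replicates 3 and 4, and proliferation genes had higher mean levels in replicates 1 and 2 in all 4 groups. MockUP 2 stood apart on the second component, at -52.8. In that library 4.86% of counts fell in the top 10 genes, against 6.25 to 6.35% in the other MockUP libraries. Its mitochondrially encoded transcripts made up 0.279% of counts against a range of up to 0.709% in MockUP. Its levels correlated with gene length at 0.396, above the other 15 libraries, and its mean for cytosolic ribosomal protein genes was -0.81 log2 units from the mean of all libraries. Results are therefore also given without MockUP 2 where that changes them.

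**Figure D1:**
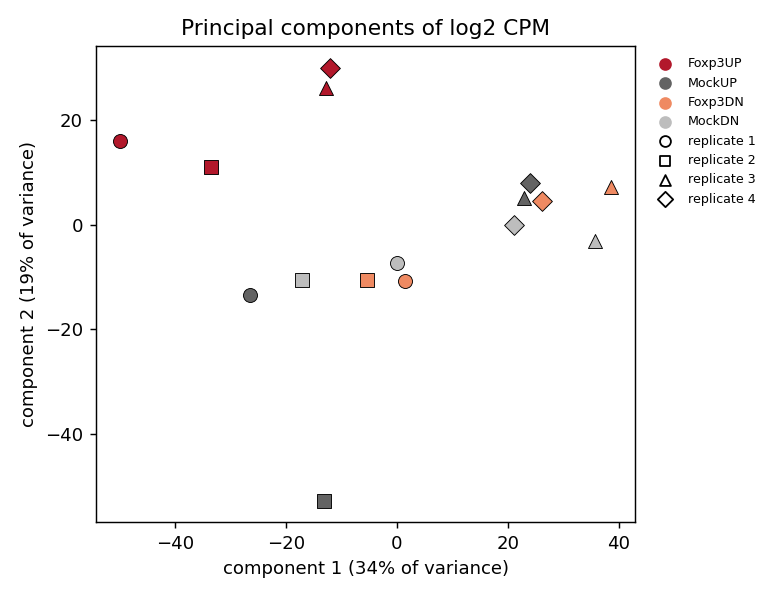
Scores of the 16 libraries on the first and second principal components of log2 CPM (axes in score units, with the percent of variance), with groups by colour and replicate numbers by symbol. MockUP 2 lies at -52.8 on the second component, and replicates 1 and 2 of each group lie to the left of its replicates 3 and 4.

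Foxp3 (ENSMUSG00000039521, X:7573644 to 7595245) was measured first, as a check of the labels. It stood at 23.6 ± 6.82 CPM in Foxp3UP, 12.4 ± 1.12 in MockUP, 10.3 ± 0.130 in Foxp3DN and 12.9 ± 1.52 in MockDN. Foxp3 was 1.89-fold higher in Foxp3UP than in MockUP (log2 fold change 0.92 ± 0.17 SE, edgeR adjusted p = 0.00233), with all 4 libraries above all 4 of MockUP. The rise was 0.56 in replicates 1 and 2, where adjusted p was 0.0671, and 1.21 in replicates 3 and 4. In Foxp3DN the log2 difference from MockDN was -0.33 ± 0.17 and did not pass (edgeR adjusted p = 1.00), although all 4 libraries lay below all 4 of MockDN. The two-sided exact permutation test gave p = 0.0286 for each pair of groups, the smallest p that it can give. That test treats all libraries as independent, which the pairing by number leaves in doubt, so its p may be too small. Whether sequence from any introduced Foxp3 construct was counted at this gene is not given in the sources used here.

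**Figure D2:**
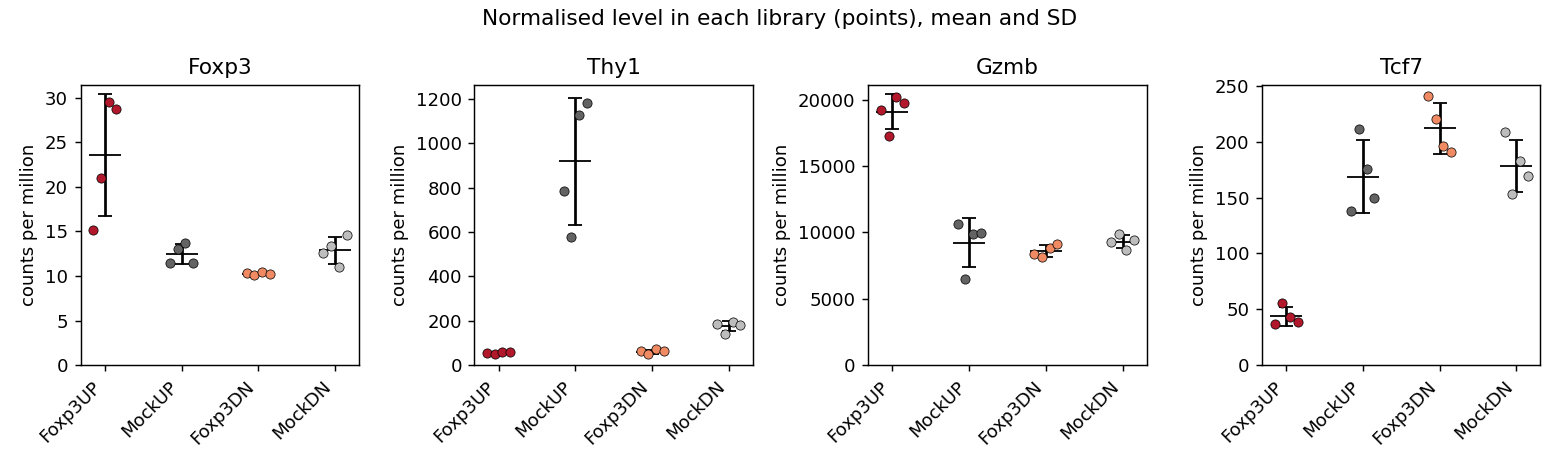
Level of Foxp3, Thy1, Gzmb and Tcf7 in CPM (vertical axes) in the 4 groups; points are libraries, and bars show mean and SD. In Foxp3UP, Foxp3 averaged 23.6 and Gzmb 19105 CPM, the highest of the 4 groups, and Tcf7 averaged 43.9 CPM, the lowest.

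The comparison of Foxp3UP with MockUP asks what differs in Foxp3-expressing cells. The genes with the largest rise were Ccr3, an eotaxin receptor, at 41.7 ± 22.6 CPM against 0.564 ± 0.308 (72.0-fold), and Mmp9, a gelatinase that degrades extracellular matrix, at 46.4 ± 19.7 against 0.941 ± 0.200 (48.8-fold). Il10, an immunosuppressive cytokine, was 9.72-fold higher, at 25.6 ± 9.41 against 2.63 ± 1.44 CPM. Gzmb, the cytotoxic protease granzyme B, was 2.07-fold higher, at 19105 ± 1310 against 9236 ± 1853 CPM, and Ctla4, an inhibitory receptor, rose from 926 ± 120 to 1866 ± 260 CPM. Tcf7, a transcription factor of naive and stem-like T cells, was 3.84-fold lower, at 43.9 ± 8.56 against 169 ± 32.5 CPM.

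Their edgeR log2 fold changes were 6.17 ± 0.47 (SE) for Ccr3 (9:124021972 to 124031689, adjusted p = 4.87e-07) and 5.61 ± 0.36 for Mmp9 (2:164940780 to 164955850, adjusted p = 8.54e-08). They were 3.28 ± 0.38 for Il10 (1:131019845 to 131024974), 1.05 ± 0.13 for Gzmb (14:56258838 to 56262260, adjusted p = 0.000109) and -1.94 ± 0.15 for Tcf7 (11:52252371 to 52283014, adjusted p = 7.49e-07). Further large rises were those of Atp6v0d2, a subunit of the proton pump V-ATPase, at 2.77, of Maf, a transcription factor that drives Il10, at 2.65, and of Klrg1, a receptor of terminal effector cells, at 2.33. Neb, which encodes the muscle protein nebulin, rose by 2.32 and Sdc4, a cell-surface proteoglycan, by 2.22. Further large falls were those of Cd163l1, a scavenger receptor, at -3.70, of Tnfrsf25, a death-domain receptor, 3.99-fold lower, of Tuba8, an alpha-tubulin, at -1.94, of Tnfsf8, the CD30 ligand, at -1.94, and of Aff3, a nuclear protein, at -1.89. Chl1, a cell adhesion molecule, was at -2.17. Thy1, which encodes CD90, was at 56.5 ± 3.95 CPM in Foxp3UP and 918 ± 287 in MockUP (-4.02 ± 0.20, adjusted p = 2.87e-09); its CD90.1 form was among the markers used to sort the cells, so its level is no finding between groups.

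In all, 1654 of 13711 genes were called, 833 higher and 821 lower, of which 181 and 94 differed at least 2-fold. With library totals in place of TMM, the split was 646 higher and 1081 lower. The groups' libraries did not overlap for 2179 genes (15.9%), including 1414 of those called. By chance 2.86% would not overlap if all libraries were independent, which the pairing by number leaves in doubt. The share was 1.15% in Foxp3DN against MockDN and 1.85% in MockUP against MockDN. With the replicate block 3475 genes were called, 1825 higher and 1650 lower, including 1651 of the 1654. Within replicates 1 and 2 alone 1360 genes were called and within replicates 3 and 4 alone 1253. Of these, 535 were called in both, all in the same direction. All 1654 had the same sign in both, which is partly built in because they were called over both sets together. The count fell to 1064 without Foxp3UP 1 and 1097 without Foxp3UP 3, and was 1830 without MockUP 2. With only the 8 libraries compared it was 658, including 652 of the 1654.

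**Figure D3:**
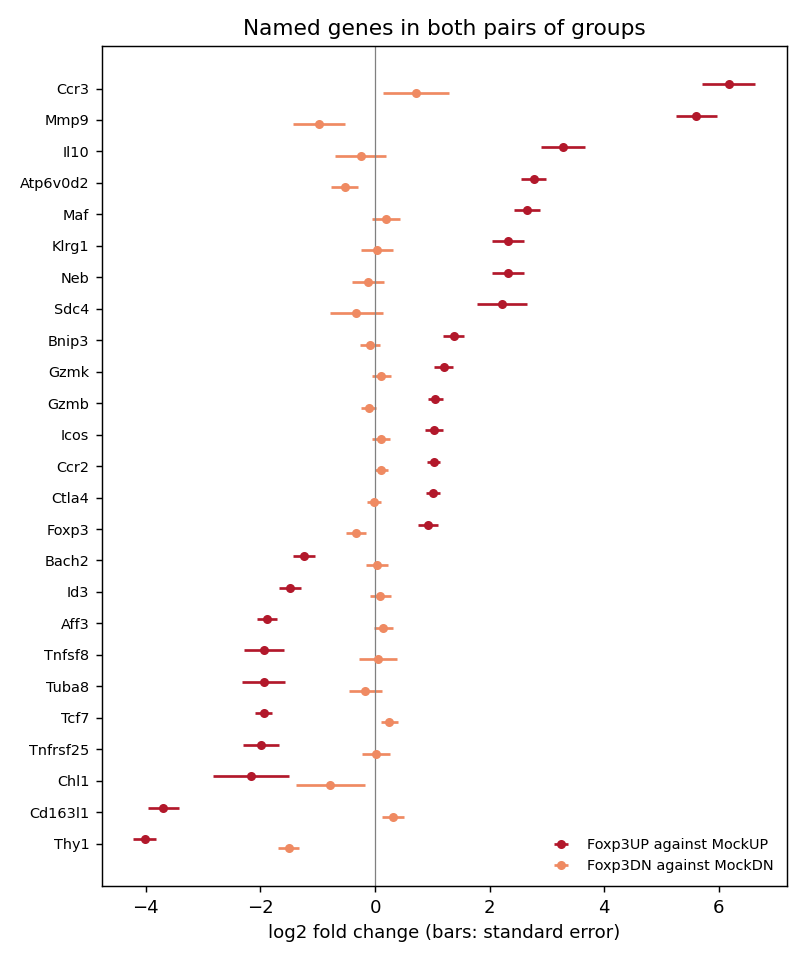
Log2 fold change (horizontal axis, bars, SE) of named genes in Foxp3UP against MockUP and in Foxp3DN against MockDN, n = 4 libraries per group. Ccr3 stood at 6.17 and Tcf7 at -1.94 in Foxp3UP; Thy1 was the only gene called in Foxp3DN.

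Genes typical of regulatory T cells rose as a group. Of 30 measured members 17 were higher, 1 lower and 12 not called (18 higher and 3 lower adjusted over the list alone, camera adjusted p = 8.20e-10, adjusted p = 0.108 with an estimated correlation). Besides Il10, Klrg1 and Ctla4 they included Itgae, the integrin subunit CD103, at 2.06, Ecm1, a secreted matrix protein, at 1.97, Tnfrsf4, the receptor OX40, at 1.06, and Icos, a co-stimulatory receptor, at 1.03. The member that fell was Cd83. Among 15 genes repressed in regulatory T cells, 3 were lower and 1 higher, and 11 were not called (3 and 1 adjusted over the list alone, adjusted p = 0.0261, adjusted p = 0.456 with an estimated correlation). Tcf7 and Cd40lg, the ligand of CD40, at -1.23, led the falls. Without MockUP 2 this list stood at adjusted p = 0.0784.

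Cytotoxic and inhibitory genes moved in both directions, and camera called neither list, while fry called the effector list higher (adjusted p = 0.0300). Of 23 genes of effector and cytotoxic molecules 6 were higher, 2 lower and 15 not called (6 and 2 adjusted over the list alone, adjusted p = 0.0784). Gzmk, a granzyme, rose by 1.20, and Prdm1, which encodes the effector transcription factor Blimp-1, by 0.78. Prf1, the pore-forming protein perforin, was called at 0.94 ± 0.29 (adjusted p = 0.0476), while Ifng, interferon gamma, stood at -0.23 (adjusted p = 0.615). The effector list passed without MockUP 3 (0.0249) and without MockUP 4 (0.0415). Of 22 genes of inhibitory receptors and exhaustion, 5 were higher, 4 lower and 13 not called (6 and 8 adjusted over the list alone, adjusted p = 0.726). Havcr2, the receptor TIM-3, rose by 0.57 and Cd101, another inhibitory molecule, by 0.72, whereas Btla, an inhibitory receptor, fell by 1.13 and Nr4a3, a nuclear receptor induced by T cell receptor signals, fell by 0.88. Pdcd1, which encodes PD-1, was at -0.39 (adjusted p = 0.103, 0.00347 with the block).

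Among 20 genes of naive, stem-like and memory cells, 4 were higher, 5 lower and 11 not called (5 and 6 adjusted over the list alone, adjusted p = 0.181). Id3, which restrains effector differentiation, fell by 1.48 and Bach2, a repressor of effector genes, by 1.24, whereas Slamf6, a receptor of stem-like cells, rose by 1.37. The tissue residence list had 4 of 16 members higher and 3 lower, with 9 not called (4 and 3 adjusted over the list alone, adjusted p = 0.580). Rgs2, a regulator of G-protein signalling, rose by 0.57 and Hic1, a transcriptional repressor, fell by 1.05. Cytokines and their receptors had 7 of 32 higher, 1 lower and 24 not called (7 and 3 adjusted over the list alone, adjusted p = 0.306); the median was -0.14 although the mean and the test pointed up. Il12rb1, a receptor chain for interleukin-12, rose by 1.28 and Ccr2, a chemokine receptor, by 1.03, and Il18rap, a chain of the interleukin-18 receptor, fell by 0.65. The T cell receptor and co-stimulation list rose, with 4 of 21 higher, 0 lower and 17 not called (4 and 0 adjusted over the list alone, adjusted p = 0.0136, adjusted p = 0.487 with an estimated correlation, 0.0851 without MockUP 1). Cd247, the zeta chain of the receptor complex, rose by 0.44 and Cd2, an adhesion receptor, by 0.61.

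Interferon-response genes rose, with 10 of 26 higher, 0 lower and 16 not called (13 and 0 adjusted over the list alone, camera adjusted p = 1.59e-07, adjusted p = 0.456 with an estimated correlation). Ifi27l2a, an interferon-induced mitochondrial protein, rose by 1.36, Oas1a, a sensor of double-stranded RNA, by 1.15, and Gbp3, a guanylate-binding protein, by 0.58. MockUP was the group with low levels of these genes: from the mean of all libraries the list stood at -0.65 to -0.20 in MockUP, -0.10 to 0.44 in Foxp3UP, 0.06 to 0.43 in Foxp3DN and -0.02 to 0.21 in MockDN (log2 units per library). The hypoxia list rose with 6 of 16 higher, 0 lower and 10 not called (9 and 0 adjusted over the list alone, adjusted p = 0.000261, adjusted p = 0.239 with an estimated correlation). MockUP tended to be low for this list too. Measured in the same way, it stood at -0.33 to 0.01 in MockUP, 0.04 to 0.39 in Foxp3UP, -0.09 to 0.09 in Foxp3DN and -0.06 to 0.10 in MockDN. Bnip3, a mitophagy receptor, went from 153 ± 49.8 to 396 ± 74.4 CPM (log2 fold change 1.37), and Bnip3l, its homologue, rose by 0.47. Early-response and dissociation-stress genes fell, with 4 of 21 lower, 0 higher and 17 not called (5 and 0 adjusted over the list alone, adjusted p = 0.000137, adjusted p = 0.456 with an estimated correlation). Egr3, an immediate-early transcription factor, fell by 0.78, with its relatives Egr1 at -0.47 and Egr2 at -0.57, and Fosb, an AP-1 component, at -1.04.

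Glycolysis genes moved apart within a list that rose, with 4 of 23 higher, 2 lower and 17 not called (8 and 2 adjusted over the list alone, adjusted p = 0.00227, adjusted p = 0.456 with an estimated correlation). MockUP tended to be low here as well: from the mean of all libraries the list stood at -0.21 to 0.04 in MockUP and -0.03 to 0.07 in MockDN, against 0.05 to 0.23 in Foxp3UP and -0.09 to 0.04 in Foxp3DN. Aldoc, an aldolase, was 2.84-fold higher and Gpi1, glucose-6-phosphate isomerase, rose by 0.42. Slc16a1, a lactate transporter, fell by 0.68 and Hk2, a hexokinase, by 0.78. Slc2a1, the glucose transporter GLUT1, was at 0.19 (adjusted p = 0.208, 0.0217 with the block). Amino acid transport and integrated stress response genes fell, with 5 of 18 lower, 0 higher and 13 not called (7 and 0 adjusted over the list alone, adjusted p = 0.00934, adjusted p = 0.456 with an estimated correlation). Slc7a5, a transporter of large neutral amino acids, fell by 0.92, Asns, asparagine synthetase, by 0.78, and Slc38a1, a glutamine transporter, by 0.42; Slc1a5, another glutamine transporter, was at -0.53.

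In pentose phosphate and one-carbon metabolism, 3 of 17 genes were lower, 0 higher and 14 not called (5 and 1 adjusted over the list alone, adjusted p = 0.0263, adjusted p = 0.470 with an estimated correlation, 0.0672 with the block). The members that fell were the folate enzymes Shmt1 at -0.86, Mthfd1 at -0.78 and Shmt2 at -0.70. The list's call also ended without MockUP 1 (0.104), Foxp3UP 3 (0.0914) or Foxp3UP 4 (0.0549). In the fatty acid oxidation list 1 of 27 was higher, 1 lower and 25 not called (1 and 0 adjusted over the list alone, adjusted p = 0.0478, adjusted p = 0.456 with an estimated correlation). Pparg, a nuclear receptor of lipid metabolism, rose by 1.37, Ppargc1b, a coactivator of mitochondrial genes, was at -0.85, and Cpt1a, which imports fatty acids into mitochondria, was at 0.09 (adjusted p = 0.822). That list's call ended without Foxp3UP 1 (0.150), Foxp3UP 2 (0.0596), MockUP 2 (0.0935), MockUP 3 (0.117) or MockUP 4 (0.0749), and with RLE size factors (0.0525).

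The other metabolic lists were not called by camera, while fry called lipid uptake, binding and storage higher (adjusted p = 0.0170). Fatty acid and cholesterol synthesis had 2 of 26 higher, 4 lower and 20 not called (2 and 5 adjusted over the list alone, adjusted p = 0.726), with a median of 0.04 where the mean and the test pointed down. Fasn, fatty acid synthase, fell by 1.08 and Acaca, acetyl-CoA carboxylase, was at -0.83, while Elovl6, an elongase, rose by 0.76 and Mvd, a mevalonate enzyme, by 0.62. Lipid uptake and storage had 1 of 17 higher, 1 lower and 15 not called (2 and 1 adjusted over the list alone, adjusted p = 0.145). Plin2, a coat protein of lipid droplets, rose by 1.13 and Scarb1, a lipoprotein receptor, was at -0.56. The tricarboxylic acid cycle had 0 of 25 higher, 1 lower (Suclg2, a succinyl-CoA ligase subunit, at -0.53) and 24 not called (0 and 1 adjusted over the list alone, adjusted p = 0.638).

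In the nuclear-encoded respiratory chain 1 of 72 genes was higher (Ndufv3, a complex I subunit, at 0.56), 0 were lower and 71 were not called (1 and 0 adjusted over the list alone, adjusted p = 0.0643). That list's direction turned with the library that stood apart: without MockUP 2 it fell (0.0158), and it rose without MockUP 3 (0.000935), without MockUP 4 (4.41e-05) and without Foxp3UP 3 (0.0488). It also rose within replicates 1 and 2 (6.33e-11) and fell within replicates 3 and 4 (0.00254). The cytosolic ribosomal proteins had 0 of 30 called in either direction, also adjusted over the list alone (adjusted p = 0.127), and fell without MockUP 2 (7.12e-09), rising within replicates 1 and 2 (0.00486) and falling within replicates 3 and 4 (3.36e-10). Mitochondrially encoded transcripts had 0 of 11 called, also adjusted over the list alone (adjusted p = 0.726), with a median of -0.01 where the mean and the test pointed up. Proliferation had 0 of 31 called, also adjusted over the list alone (adjusted p = 0.796), with Mki67, a marker of cycling cells, at 0.06 (adjusted p = 0.965). Fry, which tests whether a set's genes move on balance in 1 direction, called 15 of the 29 sets, the 10 called by camera and 5 named here with their values.

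With the replicate block more members were called in most lists. Early-response genes had 16 of 21 lower, interferon-response genes 20 of 26 higher, hypoxia 10 of 16 higher, and the regulatory T cell signature 22 higher and 3 lower of 30. Genes repressed in regulatory T cells had 7 lower and 1 higher of 15, and T cell receptor genes 9 of 21 higher. Effector genes had 11 higher and 5 lower of 23, inhibitory receptors 9 and 8 of 22, naive and memory genes 6 and 10 of 20, and cytokines and receptors 11 and 7 of 32. Among metabolic lists, glycolysis had 12 higher and 2 lower of 23, amino acid transport 8 lower of 18, and one-carbon genes 8 lower and 1 higher of 17. Fatty acid oxidation had 9 higher and 1 lower of 27, lipid uptake 8 and 1 of 17, and fatty acid and cholesterol synthesis 4 and 7 of 26. The respiratory chain had 2 higher and 1 lower of 72, the tricarboxylic acid cycle 1 and 2 of 25, and proliferation 3 higher of 31. Macrophage markers had 4 of 14 higher and melanoma markers 2 of 11.

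**Figure D4:**
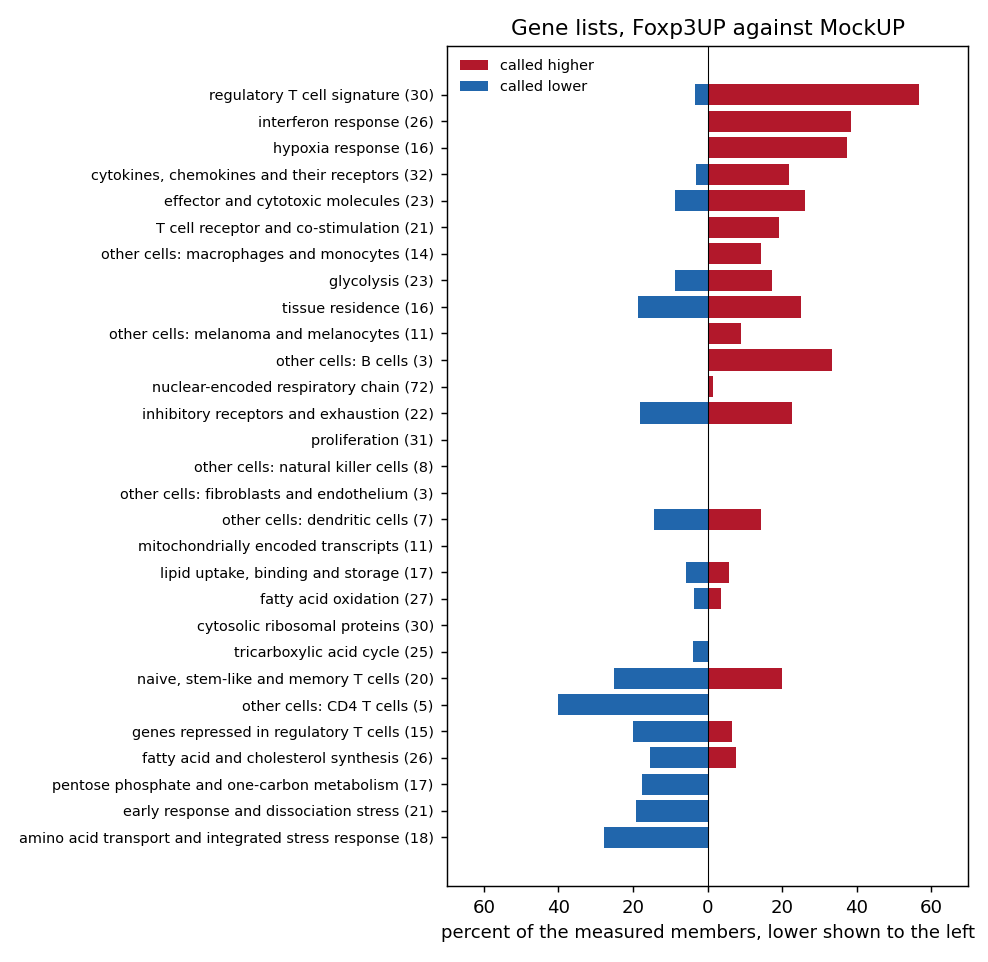
Percent of each list's measured members (number in parentheses) called higher (right) or lower (left) in Foxp3UP against MockUP, by edgeR. The regulatory T cell signature had 17 of 30 members higher, and amino acid transport had 5 of 18 lower.

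Of the T cell surface genes Cd8a, Cd8b1, Cd3e and Il2ra, none was called without the block, and 3 were higher with it. Cd8a, the CD8 alpha chain, was at 0.22 (adjusted p = 0.419, 0.0235 with the block), Cd8b1, its beta chain, at 0.27 (0.196, 0.0266 with the block), Cd3e, a chain of the T cell receptor complex, at 0.12 (0.381) and Il2ra, the interleukin-2 receptor alpha chain, at 0.30 (0.193, 0.00613 with the block). Of the lists for other cells that the sort could hold, none was called by camera, while fry called CD4 T cell markers lower (adjusted p = 0.00341) and B cell markers (0.0258) and fibroblast and endothelial markers (0.0300) higher. Markers of macrophages and monocytes had 2 of 14 higher (Cd68, a lysosomal glycoprotein, at 0.86, and Ctss, a lysosomal protease, at 0.47, adjusted p = 0.204) and melanoma markers 1 of 11 (Gpnmb, a membrane glycoprotein, at 0.81, adjusted p = 0.145). B cell markers had 1 of 3 higher (Ighm, the IgM heavy chain, at 0.85, adjusted p = 0.109), and dendritic cell markers had 1 of 7 higher (H2-Ab1, a class II histocompatibility chain, at 0.82) and 1 lower (Itgax, the integrin CD11c, at -1.45, adjusted p = 0.726), with a median of 0.02 where the mean and the test pointed down. Markers of CD4 T cells had 2 of 5 lower (Cd40lg and Trat1, an adaptor of the T cell receptor, at -1.52, adjusted p = 0.0799, or 0.0490 without Foxp3UP 3). Natural killer cell markers had 0 of 8 called (0.854) and fibroblast and endothelial markers 0 of 3 (0.159). The counts were the same adjusted over the list alone except for CD4 T cells (1 higher and 2 lower) and fibroblasts (1 higher). Too few neutrophil markers (2, of which Mmp9 was higher) and erythroid markers (1, not called) were measured for a set test. Without some libraries the filter kept more genes and the list other cells: neutrophils could be tested, and it passed without Foxp3UP 4 (higher, 0.0356).

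Of the 83 named genes called in this comparison, 66 kept the call without any single library. The edgeR call ended without 7 of the 8 libraries compared for Prf1 (adjusted p up to 0.158) and without 6 for Chl1 (0.110), Egr2 (0.118), Lef1 (0.139) and Ppargc1b (0.145). It ended without 5 for Ctss (0.122), Satb1 (0.129) and Scarb1 (0.0995), without 4 for Fosb (0.0896) and H2-Ab1 (0.0976), and without 3 for Egln3 (0.0777) and Gpnmb (0.0574). It ended without 2 for Cd2 (0.0667), Egr1 (0.0574) and P4ha1 (0.0533), and without Foxp3UP 1 for Acaca (0.0530) and Slc1a5 (0.0581).

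The comparison of Foxp3DN with MockDN covers the other pair of groups. Foxp3 RNA was not higher in Foxp3DN (log2 difference -0.33, not called), so this pair cannot show what accompanies a rise of Foxp3. Thy1, 62.1 ± 9.02 against 176 ± 23.8 CPM, was the only gene called (-1.51 ± 0.18 SE, edgeR adjusted p = 0.00317), and it is a gene of a sort marker. None of the genes called in Foxp3UP besides Thy1 was called here: Tcf7 was at 0.25, Gzmb at -0.11, Ctla4 at -0.02, Havcr2 at -0.11 and Prf1 at -0.26. Pdcd1 was at -0.18, Ifng at 0.05, Il2ra at -0.04, Slc2a1 at -0.003, Cpt1a at -0.04 and Mki67 at -0.16, and Cd8a, Cd8b1 and Cd3e were between 0.01 and 0.09, each with an adjusted p of 1.00. An unadjusted p under 0.05 was found for 143 of 13711 genes, well below the share of 0.05 that no difference would give. The main fit, which leaves out the pairing, thus gave p-values that tended to be too large here. With the replicate block 548 genes had such a p. DESeq2, limma-voom and the replicate block each called 1 gene. The groups did not overlap for 157 genes (1.15%, against 2.86% by chance if all libraries were independent). The effects correlated across genes with those in Foxp3UP at r = -0.03 (Spearman -0.03), where genes are not independent replicates, and 827 of the 1654 genes called in Foxp3UP had the same sign here.

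As sets, 9 lists passed camera in Foxp3DN although no member of any list was called, over all genes or adjusted over the list alone. None of the 9 passed with an estimated correlation or with fry. Interferon-response genes stood higher by camera (median 0.14, adjusted p = 1.43e-06, adjusted p = 0.506 with an estimated correlation), as did naive, stem-like and memory genes (0.00349, 0.506). Melanoma markers (0.00223, 0.506), markers of other cells: macrophages and monocytes (0.0343, 0.606) and mitochondrially encoded transcripts (0.00536, 0.625) stood higher too. Pentose phosphate and one-carbon genes (0.00349, 0.506), glycolysis (0.00536, 0.506), fatty acid and cholesterol synthesis (0.0343, 0.665) and proliferation (0.0455, 0.839) stood lower; in each pair the second value is the adjusted p with an estimated correlation. Only the interferon list passed without each of the 8 libraries in turn: without MockDN 2 the naive list (0.218), melanoma markers (0.218), one-carbon genes (0.101), lipid synthesis (0.640), macrophage markers (0.759) and proliferation (0.218, now up) did not, and without MockDN 3 glycolysis (0.124) and mitochondrial transcripts (0.194) did not. With the block, cytokines (0.00546), dendritic cell markers (0.00421), early-response genes (0.0147) and tissue residence (0.0357) passed camera as well, all higher. With the block and an estimated correlation 0 lists passed.

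Other single libraries ended these calls too. That of other cells: melanoma and melanocytes ended without Foxp3DN 1 (0.0608), Foxp3DN 3 (0.112) or MockDN 4 (0.124), that of other cells: macrophages and monocytes without Foxp3DN 1 (0.255) or Foxp3DN 3 (0.332), and that of mitochondrially encoded transcripts without Foxp3DN 1 (0.102) or MockDN 4 (0.0857). The call of pentose phosphate and one-carbon metabolism ended without Foxp3DN 1 (0.0833), that of glycolysis without Foxp3DN 2 (0.0908) or Foxp3DN 4 (0.0513), and that of fatty acid and cholesterol synthesis without Foxp3DN 3 (0.439), Foxp3DN 4 (0.170) or MockDN 1 (0.107). The call of proliferation ended without Foxp3DN 3 (0.600, then up), Foxp3DN 4 (0.487) or MockDN 1 (0.551).

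Further lists passed in Foxp3DN only when a library was left out. Markers of other cells: fibroblasts and endothelium were higher without Foxp3DN 2 (0.00717), Foxp3DN 4 (5.09e-05), MockDN 1 (0.00874), MockDN 3 (0.0220) or MockDN 4 (0.00290), and markers of other cells: dendritic cells without Foxp3DN 4 (0.00369) or MockDN 1 (0.00874). The list early response and dissociation stress was higher without Foxp3DN 2 (0.0215), MockDN 3 (0.00383) or MockDN 4 (0.0496), and cytosolic ribosomal proteins without Foxp3DN 2 (0.00208) or MockDN 4 (0.0490). The tissue residence list was higher without MockDN 1 (0.0420) or MockDN 4 (0.0369). Without MockDN 4 the list cytokines, chemokines and their receptors (0.0496) and markers of other cells: natural killer cells (0.0496) were higher, and without MockDN 1 the tricarboxylic acid cycle was lower (0.0360).

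The difference between the effects asks directly whether Foxp3UP and Foxp3DN differ from their own controls in different ways. It was positive for Mmp9 (6.59 ± 0.59 SE, edgeR adjusted p = 1.47e-05), Ccr3 (5.45 ± 0.80, adjusted p = 0.00212), Il10 (3.53), Atp6v0d2 (3.30), Maf (2.46), Neb (2.44), Cysltr1, a leukotriene receptor (2.59), and Tnfrsf8, the receptor CD30 (2.56). It was negative for Cd163l1 (-4.01 ± 0.34, adjusted p = 1.36e-05), Tcf7 (-2.19 ± 0.21, adjusted p = 2.33e-05), Pou6f1, a homeobox factor (-2.05), Aff3 (-2.03), Gcnt2, a glycosyltransferase (-2.02), Tnfrsf25 (-2.01) and Tnfsf8 (-1.99). Foxp3 itself differed by 1.25 ± 0.24 (adjusted p = 0.0144), Gzmb by 1.16 ± 0.18 (adjusted p = 0.00392) and Ctla4 by 1.04 ± 0.18 (adjusted p = 0.00612), as did the sort-marker gene Thy1 (-2.51).

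In all, 251 genes differed, 132 positively and 119 negatively, and 2145 had an unadjusted p under 0.05. With library totals the split was 114 and 187. With the replicate block 1739 genes differed, 895 and 844, including all 251, and the block added Prf1 (1.20, adjusted p = 0.154, or 7.27e-05 with the block), Havcr2 (0.67, 0.0765, or 0.000761) and Il2ra (0.33, 0.453, or 0.0365). Replicates 1 and 2 alone gave 70 genes and replicates 3 and 4 alone 257, with 48 shared and of the same sign. The count fell to 138 without Foxp3UP 1, 122 without Foxp3UP 3, 146 without Foxp3UP 4, 140 without MockUP 3, 151 without MockUP 4, 114 without Foxp3DN 3, 110 without Foxp3DN 4, 99 without MockDN 1, 113 without MockDN 2 and 130 without MockDN 4. It was 518 without MockUP 1. Of the 46 named genes that differed, 28 kept the call without any single library; of those named here, the call ended without at least 1 library for Cysltr1, Tnfrsf8 and Tnfsf8. DESeq2 called 666 genes.

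The regulatory T cell signature had 12 of 30 members with a positive difference, 0 negative and 18 not called (18 and 1 adjusted over the list alone, camera adjusted p = 2.32e-10, adjusted p = 0.0905 with an estimated correlation), with Klrg1 at 2.30 and Izumo1r, the folate receptor FR4, at 2.08. Glycolysis differed positively, with 2 of 23 positive and 1 negative (6 and 2 adjusted over the list alone, 0.000137, adjusted p = 0.360 with an estimated correlation), led by Aldoc at 1.55. Hypoxia differed positively, with 1 of 16 called, Bnip3 at 1.46 (6 and 0 adjusted over the list alone, 0.000744, adjusted p = 0.273 with an estimated correlation). Glycolysis and hypoxia stood lower in MockUP than in MockDN (medians -0.10 and -0.17), so their rises in Foxp3UP and these differences include a low control. The interferon list had 1 of 26 positive (4 and 0 adjusted over the list alone, 0.00148, adjusted p = 0.588 with an estimated correlation), and this difference includes the low level of these genes in MockUP. Fatty acid oxidation had 1 of 27 positive, Pparg at 1.79 (1 and 0 adjusted over the list alone, 0.0226, adjusted p = 0.553 with an estimated correlation, 0.0677 without Foxp3UP 1).

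Early-response genes differed negatively with 0 of 21 called, also adjusted over the list alone (5.61e-05, adjusted p = 0.553 with an estimated correlation), and so did amino acid transport and integrated stress response with 0 of 18 (0.0228, adjusted p = 0.553 with an estimated correlation, 0.0641 without Foxp3UP 1 and 0.0683 without MockUP 2). Genes repressed in regulatory T cells had 2 of 15 negative (0 and 2 adjusted over the list alone, 0.0106, adjusted p = 0.553 with an estimated correlation). The list of naive, stem-like and memory T cells had 3 of 20 negative, Tcf7, Id3 at -1.57 and Bach2 at -1.27 (1 and 3 adjusted over the list alone, 0.0282, adjusted p = 0.553 with an estimated correlation). That call ended without Foxp3UP 1 (0.0857), MockUP 2 (0.0777), Foxp3DN 4 (0.0524) or MockDN 2 (0.0503). Among markers of other cells: CD4 T cells had 2 of 5 negative (1 and 3 adjusted over the list alone, 0.0420, adjusted p = 0.273 with an estimated correlation, 0.0677 with the block). That call also ended without MockUP 2 (0.0683), Foxp3DN 1 (0.0621), Foxp3DN 2 (0.0730) or MockDN 4 (0.0637). With the block the proliferation list passed camera as well (adjusted p = 2.43e-05), but with the block and an estimated correlation 0 lists passed. Fry called 4 of 29 sets (the regulatory T cell signature, glycolysis, hypoxia and CD4 T cells). Without MockUP 2 the difference also passed, negatively, for cytosolic ribosomal proteins (1.03e-09), mitochondrially encoded transcripts (0.00213) and the nuclear-encoded respiratory chain (0.0171). The other lists were not called by camera with all libraries, at an adjusted p of 0.0512 or above, and the cytokine list had a median and mean below 0 where the test pointed up.

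Some lists passed for the difference only when a library was left out. T cell receptor and co-stimulation passed, positively, without Foxp3UP 1 (0.0116), Foxp3UP 2 (0.0366), MockUP 3 (0.0125), MockUP 4 (0.0152), Foxp3DN 3 (0.0146), MockDN 1 (0.0377) or MockDN 2 (0.0163). The nuclear-encoded respiratory chain passed positively without MockUP 3 (0.00342), MockUP 4 (0.000341) or Foxp3DN 3 (0.00914), and effector and cytotoxic molecules without MockUP 3 (0.0366) or MockUP 4 (0.0480). The cytosolic ribosomal proteins passed negatively without Foxp3UP 4 (0.0220), MockUP 1 (0.0378), Foxp3DN 1 (0.0329), Foxp3DN 2 (0.00708), MockDN 1 (0.0371) or MockDN 4 (0.0275). The proliferation list passed positively without MockUP 1 (0.0358) or MockDN 3 (0.0350), and pentose phosphate and one-carbon metabolism negatively without Foxp3UP 1 (0.0472). Where the filter kept enough genes, the list other cells: neutrophils, which holds Mmp9, passed positively without Foxp3UP 2 (0.0366), Foxp3UP 4 (0.0271), MockUP 3 (0.0445), Foxp3DN 3 (0.0479), MockDN 2 (0.0323) or MockDN 3 (0.0469).

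With the block more members differed here too. Early-response genes had 13 of 21 negative and amino acid transport 7 of 18, where none was called without it. The regulatory T cell signature had 21 positive and 2 negative of 30, interferon-response genes 9 positive of 26, hypoxia 7 of 16, and glycolysis 10 positive and 2 negative of 23. Naive and memory genes had 9 negative and 2 positive of 20, genes repressed in regulatory T cells 5 negative and 1 positive of 15, fatty acid oxidation 4 positive and 1 negative of 27, and proliferation 8 positive of 31.

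The comparison of MockUP with MockDN shows how far the control groups of the arms differ. Thy1 was 918 ± 287 CPM in MockUP and 176 ± 23.8 in MockDN (log2 fold change 2.38 ± 0.19 SE, edgeR adjusted p = 4.17e-06) and was the only gene called. An unadjusted p under 0.05 was found for 433 of 13711 genes, again below the share of 0.05 that no difference would give, and for 723 with the replicate block. DESeq2 called 10 genes (1 higher and 9 lower) and limma-voom 1. Interferon-response genes stood lower in MockUP, with a median of -0.60, 0 of 26 called and 19 lower adjusted over the list alone (camera adjusted p = 1.07e-31, adjusted p = 0.0661 with an estimated correlation, fry adjusted p = 0.0386). Without MockUP 3, Rsad2, an interferon-induced antiviral enzyme, was called lower as well. Melanoma markers stood higher, with 0 of 11 called and 2 higher adjusted over the list alone (3.31e-11, adjusted p = 0.166 with an estimated correlation).

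Hypoxia (0.000303, adjusted p = 0.166 with an estimated correlation, or 0.0370 with the block as well) and glycolysis (0.000467, adjusted p = 0.514 with an estimated correlation, and 0.105 by camera without MockUP 4) stood lower in MockUP. The respiratory chain (1.86e-06, adjusted p = 0.955 with an estimated correlation) and cytosolic ribosomal proteins (0.00245, adjusted p = 0.955 with an estimated correlation) stood lower too, and both stood higher without MockUP 2 (5.34e-05 and 0.01004). The ribosomal call ended without MockUP 1 (0.111). Without MockUP 2 further lists passed, with the tricarboxylic acid cycle (0.0105), mitochondrially encoded transcripts (5.34e-10) and markers of other cells: natural killer cells (0.0102) higher, and amino acid transport and integrated stress response (0.0382) and early response and dissociation stress (0.0239) lower. Proliferation stood higher (0.00245, adjusted p = 0.955 with an estimated correlation), but not without MockUP 1 (0.913), MockDN 3 (0.908) or MockDN 4 (0.103). No member of these lists was called, also adjusted over the list alone. With the block, T cell receptor genes (0.00863) and effector genes (0.0219) stood lower by camera as well. With the block and an estimated correlation only 1 list passed, the hypoxia list.

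Besides the lists given without MockUP 2, some passed when another library was left out. T cell receptor and co-stimulation was lower without MockUP 3 (0.00573), MockUP 4 (0.00864), MockDN 1 (0.0457) or MockDN 2 (0.00508), and effector and cytotoxic molecules without MockUP 3 (0.0161) or MockDN 3 (0.0203). Without MockDN 2 amino acid transport and integrated stress response (0.0381) and early response and dissociation stress (0.00265) were lower. Markers of other cells: fibroblasts and endothelium were higher without MockUP 1 (0.00956), MockUP 3 (0.0161), MockDN 1 (0.0333) or MockDN 4 (0.0112), and mitochondrially encoded transcripts without MockDN 1 (0.0195).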

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

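The counts over other splits of the samples and the test of eosinophil RNA were set before their results were seen; the tests of gene length, of the sets of replicates, and of RNA from neutrophils, macrophages and CD4 T cells were chosen only after the result was seen.

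In Foxp3UP against MockUP, 1654 genes were called, and 1 of the 35 splits of the 8 libraries (2.86%) gave as many, the real one. The highest other split gave 461 and parted replicates 1 and 2 from 3 and 4. A chance arrangement of these libraries is thus an unlikely source if all splits are treated alike. Since libraries pair by number, only the 8 splits that part all 4 replicate pairs compare like with like. Among these the others called 0 genes, but 1 in 8 is the smallest share they can give, which is too coarse to exclude chance. With the gene length trend removed from each library, 88.1% of the 1654 genes (1457) kept call and sign. The share was 99.1% where the replicate block was added as well (99.8% with the block alone), which argues against gene length as the whole cause. In both sets of replicates 535 genes were called with the same sign. A difference between the sets is balanced over both groups, so this count cannot test it as a cause. What remains open is any difference between the groups that is not due to Foxp3, which the design cannot separate from the group. A sort by different markers would be such a difference, but the labels do not say which markers each group was sorted by. A difference that follows Foxp3 expression may be the source, as a hypothesis found and tested on the same libraries.

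Mmp9, Cd68 and Ctss, genes of neutrophils and macrophages, and Ccr3, a gene of eosinophils, were higher in Foxp3UP. The neutrophil transcripts S100a8 and S100a9 together differed by -0.0806 CPM (SE 0.115) where Mmp9 rose by 45.5 CPM, and eosinophil transcripts (Prg2, Epx, Ear1, Ear2, Ear6, Siglecf and Alox15, nearly all of it Siglecf) differed by 2.54 CPM (SE 1.99) where Ccr3 rose by 41.1. The macrophage transcripts Lyz2, Apoe, C1qa, C1qb and C1qc differed by 2.22 CPM (SE 3.54) where Cd68 rose by 10.2 CPM (SE 2.63), a gap per library of 7.94 CPM (SE 1.89), and Ctss by 28.0 CPM (SE 10.8), a gap of 25.7 CPM (SE 9.55). These values argue against such cells as the whole source, if the listed transcripts are at least as abundant in them as the genes that rose. Expression of these genes by the sorted CD8 T cells themselves may account for the rise and was not tested. Ctss stood at 99.9 ± 15.7 CPM in Foxp3UP, 72.0 ± 14.9 in MockUP, 95.6 ± 7.72 in Foxp3DN and 83.6 ± 10.3 in MockDN. The rise of Ctss thus includes a low level in MockUP.

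The 17 genes of the regulatory T cell signature that rose gained 2255 CPM together. CD4 regulatory T cells in the sort could bring these transcripts, but Cd4 differed by 0.239 CPM (SE 0.121; 0.489 against 0.250 CPM), where 5% of the signature's rise is 113 CPM. This argues against such cells as the source, if Cd4 reaches at least 5% of these genes' summed level in them. That share was assumed and not measured here. Expression within the CD8 T cells remains open as a hypothesis.

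The single Thy1 call in Foxp3DN against MockDN was matched by 2 of 35 splits, the real one included, with 1 gene in the highest other, so chance cannot be excluded by this count, which says little about a single gene. Thy1 itself did not overlap between the groups (50.6 to 72.7 against 142 to 196 CPM) and was called under all 24 alternatives. In MockUP against MockDN 2 of 35 splits gave as many as the 1 gene called, with 948 in the split of replicates 1 and 2 from 3 and 4, which points to a structure of the samples; the block gave 1. In both comparisons the other splits that part all 4 pairs gave 0. For the difference of effects, 5 of 100 splits gave at least 251 genes, the real one included, with 1119 in the highest other. This count can neither exclude chance nor point to it, because the other splits that gave as many kept structure of the real samples. The split with 1119 kept the true UP grouping, and the others (1043, 857 and 445) grouped the libraries mostly by replicate number, which points to a structure of the samples. Of the 100 splits 6 parted all 8 pairs, and besides the real one they gave 0. The block gave 1739.

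Single libraries lay far from the other 3 of their group for 5 of 140 group values, where about 1 in 20, or 7, would by chance. The share of counts in the top 10 genes was 7.30% in Foxp3UP 2 (8.00 to 8.09% in the others) and 4.86% in MockUP 2 (6.25 to 6.35%). Klrg1 was at 14.6 CPM in Foxp3UP 3 (11.1 to 11.6), Sdc4 at 0.955 CPM in MockDN 4 (2.13 to 2.32) and Tuba8 at 3.53 CPM in MockUP 3 (1.75 to 1.99).

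The effects in Foxp3UP and Foxp3DN differed for 251 genes, 46 of them named by the rule. Log2 differences of 2 and more were those of Mmp9 (6.59), Ccr3 (5.45), Il10 (3.53), Atp6v0d2 (3.30), Cysltr1 (2.59), Tnfrsf8 (2.56), Maf (2.46), Neb (2.44), Klrg1 (2.30) and Izumo1r (2.08). Positive differences between 1 and 2 were those of Itgae (1.94), Pparg (1.79), Aldoc (1.55), Bnip3 (1.46), Il12rb1 (1.43), Plin2 (1.36), Tnfrsf4 (1.27), Foxp3 (1.25), Gzmb (1.16), Gzmk (1.09) and Ctla4 (1.04). Below 1 were those of Icos (0.92), Ccr2 (0.92), Prdm1 (0.81), Ighm (0.78), Gbp3 (0.56) and Gpi1 (0.53). Negative differences were those of Shmt2 (-0.64), Mthfd1 (-0.66), Shmt1 (-0.74), Slc16a1 (-0.76), Il18rap (-0.76), Btla (-1.26), Bach2 (-1.27), Cd40lg (-1.34), Id3 (-1.57), Itgax (-1.57), Trat1 (-1.81) and Tnfsf8 (-1.99). The lowest were those of Tnfrsf25 (-2.01), Gcnt2 (-2.02), Aff3 (-2.03), Pou6f1 (-2.05), Tcf7 (-2.19), the sort-marker gene Thy1 (-2.51) and Cd163l1 (-4.01). Without at least 1 single library the difference was not called for Bach2, Btla, Cd40lg, Cysltr1, Gbp3, Gpi1, Gzmk, Icos, Ighm, Itgae, Mthfd1, Pparg, Prdm1, Shmt1, Shmt2, Slc16a1, Tnfrsf8 and Tnfsf8.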

How the results depend on the processing

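Length correction, fits within replicates 1 and 2 or 3 and 4, and the block without MockUP 2 were chosen only after the result was seen. In Foxp3UP against MockUP, where 1654 genes were called, the replicate block gave 3475, a term for the sets of replicates 2567, the block with length correction 3909, the block without MockUP 2 4196, the 8 libraries compared alone 658, and the 2-fold threshold 275; leaving out each library gave 1064 to 1978. For the difference of effects (251), the block gave 1739, the term 938, DESeq2 666, the block with length correction 2093, the block without MockUP 2 3051, replicates 1 and 2 alone 70, and the 2-fold threshold 116; leaving out each library gave 99 to 518. MockUP against MockDN (1) gave 2 genes with no filter and in replicates 1 and 2, 10 with DESeq2, and 1 to 2 without each library. Fewer libraries and the 2-fold threshold narrow what can pass. The fit to the 8 libraries alone also estimates the spread without the DN arm, and in it 652 of the 1654 genes (39.4%) kept call and sign. Which of these lowers the count was not tested, nor was the cause of the other shifts. Foxp3DN against MockDN gave 1 gene under all 24 alternatives. Foxp3 in Foxp3UP was higher under all 24 alternatives and called under 23. It was not called in replicates 1 and 2, at a log2 change of 0.56 (edgeR adjusted p = 0.0671). Its adjusted p ranged from 1.22e-05 to 0.0671 over the alternatives, and leaving out each library gave log2 changes of 0.79 to 1.08. In Foxp3DN it was not called under any of 23, at -0.40 to -0.27. With an estimated correlation 0 lists passed in each of the 4 comparisons without the block, and with it hypoxia passed in MockUP against MockDN (0.0370); fry passed 0 in Foxp3DN, 4 for the difference and 1 in MockUP. Without each library, 3 to 13 lists passed in Foxp3DN, 6 to 12 in MockUP, 8 to 11 in Foxp3UP and 9 to 14 for the difference. The correlation of the effects in both arms stayed at -0.03 in its 3 alternatives. Over all alternatives, 2095 of 2300 values of the named genes stayed on the same side of the threshold in Foxp3UP, 186 were weaker, 19 stronger and 0 reversed; for the difference these were 1643 of 1856, 194, 19 and 0, and in Foxp3DN all 384 stayed uncalled or called as before. Among genes not called, the sign changed in 10, 7 and 39 of these values. Many of the named genes were chosen for large or clear effects in these libraries, so their stability is partly built in. Of all 1654 genes called in Foxp3UP, 61.5% (without Foxp3UP 1) to 91.2% (without MockUP 1) kept call and sign when 1 library was left out. With the block more members of most lists and families were called, as given beside them. Among the named genes and the lists tested by camera with the preset correlation, the block changed no other call besides those given with it. In simulation 20.9% of 1.5-fold changes were recovered for Foxp3UP and 8.96% for the difference of effects. The simulated data held far fewer changed genes (134 calls for Foxp3UP) than were called in the real comparison. Among the 1654 genes called there, the median absolute log2 fold change was 0.60, so the simulation does not set the limit for Foxp3UP. The simulated libraries also lacked the pairs and sets of replicates of the real ones, so real recovery may be lower. Where few genes were called, as in Foxp3DN, changes of 1.5-fold and larger may have been missed.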

Other observations

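The 6 gene families were written down, and their tests chosen, only after the most changed genes of Foxp3UP against MockUP had been seen, so they describe these libraries and are no independent evidence.

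Genes of ribosome biogenesis fell in Foxp3UP: 39 of 44 were called lower and 0 higher (adjusted Fisher exact p = 4.25e-42 over the 6 families; camera adjusted p = 0.0370 with an estimated correlation). Among them were Utp20, a processing factor of the small subunit, at -1.16, Polr1b and Polr1a, subunits of RNA polymerase I, at -1.11 and -0.92, Heatr1, an rRNA synthesis factor, at -0.92, and Nop2, a nucleolar methyltransferase, at -0.87. Nucleotide synthesis had 10 of 28 lower and 0 higher (adjusted p = 3.29e-06 by Fisher's exact test), including Cad, the first enzyme of pyrimidine synthesis, at -1.09, Pfas and Gart, enzymes of purine synthesis, at -1.02 and -0.74, and Ctps, CTP synthase, at -0.79. Cytosolic aminoacyl-tRNA synthetases had 9 of 20 lower and 0 higher (adjusted p = 1.31e-06 by Fisher's exact test), with Iars at -0.69, Lars at -0.56 and Eprs at -0.52. The number called lower ran from 29 to 44, 6 to 12 and 5 to 11 in these families when each library was left out in turn. Nucleotide synthesis fell to 6 genes without Foxp3UP 1, 2 or 3 or MockUP 3 or 4, and the synthetases to 5 without Foxp3UP 3, MockUP 3 or MockUP 4 and 6 without Foxp3UP 1 or 2. With the replicate block 42, 11 and 17 genes were lower and 1 nucleotide synthesis gene was higher, with the 8 libraries compared alone 28, 5 and 4, and with the 2-fold threshold 2, 2 and 0. None of their members was called in Foxp3DN by edgeR.

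Lysosomal genes rose, with 18 of 49 higher and 0 lower (adjusted Fisher exact p = 6.15e-10; camera adjusted p = 0.0203 with an estimated correlation). Besides Atp6v0d2 they included Gm2a, a ganglioside activator, at 1.07, Ctsd, the protease cathepsin D, at 0.80, and Npc2, a cholesterol carrier, at 0.74. Chemokine receptors had 8 of 15 higher and 1 lower (adjusted p = 1.31e-06 by Fisher's exact test), with Ccr4 at 1.70, Ccr1 at 1.24 and Cxcr3 at 0.71, while Cx3cr1 was at -1.38. Integrins had 4 of 18 higher and 2 lower (adjusted p = 0.0209 by Fisher's exact test), with Itga7 at 2.88 and Itgb7 at 0.98 higher and Itgb1 at -0.82; with an estimated correlation camera gave adjusted p = 0.251. Leaving out each library gave 12 to 19 lysosomal genes, 7 to 8 chemokine receptors and 4 to 8 integrins higher, with 8 integrins without MockUP 2. With the block 26 lysosomal genes were higher and 1 lower, as were 8 and 3 chemokine receptors and 8 and 3 integrins. With the 8 libraries compared alone 10, 7 and 4 were higher, and with the 2-fold threshold 2, 4 and 2. None of these genes was called in Foxp3DN by edgeR.

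A lower rate of ribosome production in the Foxp3UP cells is a possible explanation of the falls in the first families, where 39 of 44 ribosome biogenesis genes were lower. The family was chosen after its genes were seen and Fisher's exact test treats them as independent, so its adjusted p of 4.25e-42 is no evidence for this explanation. Of the cytosolic ribosomal proteins themselves 0 of 30 were called, and as a list they fell without MockUP 2 (adjusted p = 7.12e-09) and within replicates 3 and 4 (3.36e-10), but rose within replicates 1 and 2 (0.00486). Their direction thus depends on the libraries used and decides nothing here. No measure of rRNA or protein synthesis was used here, so this remains a hypothesis.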
